A study of Homo sapiens with 12 samples.

How the data were processed

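MicroRNAs were measured on the NanoString nCounter platform in RNA from formalin-fixed, paraffin-embedded primary cutaneous melanomas of 12 patients, each sample from a separate patient. Per the labels' protocols, RNA was extracted from 4 scrolls of 20 µm and 100 ng entered each assay. The labels give 1 factor, ulceration, with 6 ulcerated and 6 non-ulcerated tumours. They give no batch, pairing or cartridge. Samples are numbered within each group in the order of deposit, and the numbers pair nothing.

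The deposited values are a score in the sense of scaled counts rounded to whole numbers, not raw counts. This was inferred from the values: the 6 positive control probes sum to between 24064 and 24066 in every sample, while the sums over all miRNA probes differ between samples. The authors' software for scaling and its version are not given in the sources used here. The deposited probe names carry a correction factor for each probe, which is above 0 for 20 probes (0.004 to 0.128) and 0 for the rest. Of the 153 values equal to 1 in the table, 151 belong to these 20 probes, as a subtraction with a lower bound of 1 would leave. That the subtraction was the factor times the highest positive control (POS_A) is an assumption used only in an alternative. Of the 798 human miRNA probes, 21 read several miRNAs at once and are named by all of them. Such a probe belonged to a list only if each of its miRNAs did.

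Because the values are not raw counts, a model for counts was not used. They were taken without further rescaling as log2(value + 1) and compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low miRNAs, except where the subtraction left values at or near 1. Control and messenger RNA probes were left out of the test. The background floor was the mean plus 2 SD of the 8 negative control probes over all samples, 70.6. A miRNA was tested if it exceeded the floor in at least 6 samples, which kept 115 and left out 683, 619 of which never exceeded it and 64 of which did so in 1 to 5 samples. Single measures per sample were compared by exact permutation over all 924 relabellings, two-sided, whose smallest possible p is 0.00216. Lists of miRNAs were compared with camera (preset correlation of 0.01, at least 3 tested members). An estimated correlation and fry served as alternatives. Correlations used 100000 resamples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

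The design, the filter, the 21 lists and the rule for named miRNAs were fixed before the data were examined. The rule names the 12 miRNAs with the largest log2 fold change in each direction among those past the threshold. Where fewer than 10 pass, it adds the 10 with the smallest unadjusted p. It also names 20 miRNAs fixed in advance, whatever their result, and for each list that passes the 3 members with the smallest p. miRNAs named outside this rule (let-7a-5p, let-7b-5p, miR-4454, miR-7975, miR-19b-3p, miR-23a-3p, miR-25-3p, miR-29b-3p, miR-144-3p, miR-181a-5p, miR-181b-5p, miR-181d-5p, miR-342-3p and miR-494-3p) were chosen after their values were seen. Lists with fewer than 3 tested members were not tested: melanocyte lineage, myeloid, erythrocyte, endothelial, skeletal muscle, miR-34 family, miR-183 cluster, the imprinted cluster on chromosome band 14q32, the placental cluster C19MC, neural and liver.

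The closest pair of samples differed by a median absolute log2 difference of 0.395 over the tested miRNAs, against a median of 0.829 over the 66 pairs, so no sample was a copy of another. The number of samples and the spread between patients limit the precision: the median standard error was 0.52 on the log2 scale. The script was tested on simulated data with the spread of these samples, 115 miRNAs of which 40 changed, in 50 runs. It called 28.8%, 78.4%, 95.6% and 99.2% of the miRNAs changed 2-fold, 4-fold, 8-fold and 16-fold, and 3.27% of all calls were false. p-values of limma's fit per miRNA and of the exact permutation tests measure the spread between patients. Those of camera with its preset correlation treat the miRNAs of a list as nearly independent, so they do not measure that spread alone.

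Alternatives were 4 rescalings fixed in advance (median of ratios, the 100 most abundant miRNAs, the total and the messenger RNA probes), quantile normalisation, array weights, robust and untrended eBayes, exact permutation per miRNA, pseudocounts of 0.5 and 10, other filters, subtraction of the floor, and leaving out each sample. Chosen after seeing the data were rescaling to the 3 ligation controls, adding back or leaving out the corrected probes, leaving out 2 samples with low control or total signal, and miR-451a as a covariate. Messenger RNA data other than the 5 probes on this panel were not analysed here. No genomic coordinates are given, because the sources used here name no genome build.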

Results

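MicroRNA levels were measured in formalin-fixed, paraffin-embedded primary cutaneous melanomas from 12 patients, 6 with histological ulceration and 6 without. Ulceration is the loss of the intact epidermis over the tumour. The nCounter assay counts single miRNA molecules with fluorescent barcodes after a tag has been ligated to each miRNA. The panel held 828 features, of which 798 were human miRNA probes and 30 were controls or messenger RNA probes. Scaled values summed to between 139067 and 505146 per sample over the 798 miRNA probes. Of these probes, 619 never exceeded the background floor of 70.6. The 115 probes above the floor in at least 6 of the 12 samples were compared between the groups.

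The panel was dominated by a single probe that reads miR-4454 and miR-7975 together. It held 64.0% ± 4.87 (SD, n = 6) of the miRNA signal in ulcerated and 63.2% ± 7.38 (SD, n = 6) in non-ulcerated tumours, and the difference was within the spread (exact permutation test, two-sided, p = 0.846). Next came let-7a-5p, with a mean of 15615 ± 6692 (SD, n = 12), let-7b-5p with 5157 ± 2733, miR-29b-3p with 4944 ± 7110, miR-23a-3p with 4304 ± 2147 and miR-21-5p with 3430 ± 1525. The mean of miR-29b-3p rests on non-ulcerated sample 4 and was 3003 without it. Total signal was 300833 ± 124462 (SD, n = 6) in ulcerated and 277813 ± 111207 (SD, n = 6) in non-ulcerated tumours, a mean log2 difference of 0.12 (exact permutation test, p = 0.738). The number of miRNAs above the floor was 115.3 ± 19.1 (SD, n = 6) and 115.5 ± 20.7 (SD, n = 6), respectively (exact permutation test, p = 1). The ulcerated tumours minus the non-ulcerated ones differed by a mean log2 of -0.25 on the ligation controls (exact permutation test, p = 0.117). The spike-in probes read close to background, with mean log2 values of 4.26 and 4.57 against 4.26 and 4.33 for the negative controls. Their mean log2 difference was -0.31, before adjustment only (exact permutation test, p = 0.0195, adjusted p = 0.156 over 8 measures). Values this close to background give no reliable size.

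**Figure D1:**
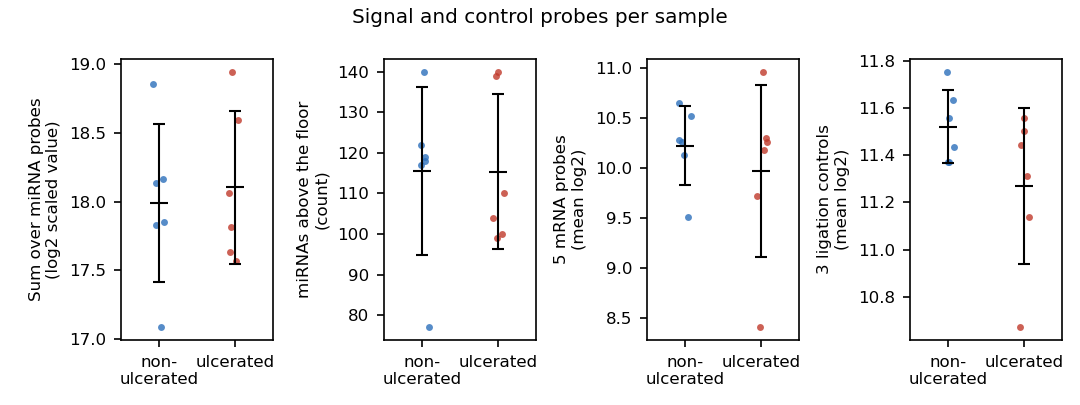
Signal and control probes per sample in 6 non-ulcerated (blue) and 6 ulcerated (red) tumours. Each point is 1 sample, the long bar is the mean and the whiskers are ± 1 SD; from left to right, the vertical axes give the log2 sum of scaled values over the 798 miRNA probes, the number of miRNAs above the floor, the mean log2 value of 5 messenger RNA probes and the mean log2 value of 3 ligation controls. The groups overlap on all 4 measures.

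The comparison of ulcerated with non-ulcerated tumours asks which miRNAs differ with this adverse histological feature. The miRNA with the smallest p was miR-223-3p, a miRNA abundant in neutrophils and other myeloid cells. Its mean was 588.5 ± 319 (SD, n = 6) in ulcerated and 215 ± 143.9 (SD, n = 6) in non-ulcerated tumours, 2.92-fold by the fitted log2 means, and 6 of 6 ulcerated tumours lay above the non-ulcerated median. Its log2 fold change was 1.54 ± 0.53 (SE), with a 95% confidence interval of 0.42 to 2.67. miR-363-3p, a member of a paralogous copy of the miR-17-92 cluster, averaged 446 ± 232 (SD, n = 6) against 166.5 ± 50.4 (SD, n = 6), 2.34-fold. Neither passed the threshold in limma after Benjamini-Hochberg adjustment, with adjusted p of 0.658 and 0.713.

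No miRNA passed the adjusted threshold of 0.05: limma called 0 of the 115 tested miRNAs, against 5 at an unadjusted p under 0.05, 3 higher and 2 lower in ulcerated tumours, where chance alone would give 5.75. The direction of such miRNAs depended on the setting, with 2 higher and 12 lower under array weights and 12 higher and 1 lower after rescaling to the ligation controls. An exact permutation test per miRNA also called 0, with 8 at an unadjusted p under 0.05. Since its smallest possible p is 0.00216, a lone miRNA could not have passed adjustment over 115 in this test, so its 0 adds little. The median 95% confidence interval reached 1.11 on the log2 scale to either side of the estimate. In simulated data of the same size and spread, with 40 of the 115 miRNAs changed at once, a 2-fold change was called for 28.8% and a 4-fold change for 78.4%. Changes of about 2-fold would thus mostly not have been detectable here. With fewer changed miRNAs the adjustment is stricter, so these rates overstate the chance of finding a lone change.

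Both miRNAs with lower values and an unadjusted p under 0.05 were read by probes from which a fixed correction had been subtracted. miR-579-3p averaged 384 ± 401 (SD, n = 6) in ulcerated and 1344 ± 808 (SD, n = 6) in non-ulcerated tumours, a log2 fold change of -3.80 ± 1.33 (SE, limma adjusted p = 0.658), with 6 of 6 ulcerated tumours below the non-ulcerated median. Of its ulcerated values 3 lay under the floor, 1 of them at the lower bound of 1, so this size rests on values that hold only a bound. With values under the floor raised to it, the difference was -2.29. With the correction added back, its log2 fold change was -0.49 ± 0.20 (SE, limma adjusted p = 0.645). miR-378e averaged 122.5 ± 55.4 (SD, n = 6) against 252 ± 107 (SD, n = 6), a log2 fold change of -1.06 ± 0.43 (SE, limma adjusted p = 0.713). With the correction added back, it was -0.37 ± 0.16 (SE, limma adjusted p = 0.682).

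The other miRNAs among the 10 with the smallest p all had higher mean values in ulcerated tumours, and none passed the adjusted threshold. miR-222-3p, which targets the cell cycle inhibitor p27 and the receptor KIT in melanoma cells, averaged 591 ± 242 (SD, n = 6) against 322 ± 99.8 (SD, n = 6), a log2 fold change of 0.86 ± 0.41 (SE), or 0.548 with array weights. Of its 6 ulcerated values, 6 lay above the non-ulcerated median, and its exact permutation p was 0.00649 before adjustment against a limma adjusted p of 0.823. miR-30d-5p averaged 609.7 ± 294 (SD, n = 6) against 325.5 ± 219 (SD, n = 6), and miR-30a-5p averaged 252 ± 185 against 120.0 ± 58.0. Their log2 fold changes were 1.16 ± 0.55 and 1.01 ± 0.49 (SE). With array weights they were 0.478 and 0.313, and that of miR-30d-5p was 0.749 without non-ulcerated sample 5. With each sample left out in turn, the 2 log2 fold changes reached at most 1.43 and 1.18. The highest values over their alternatives, 2.29 and 2.81, came with the floor subtracted, which sets values under it to a low bound. Of the values of miR-30a-5p, 2 non-ulcerated ones lay under the floor, and raised to it they gave a difference of 0.859. miR-574-5p (124 ± 50.5 against 71.7 ± 28.2), miR-148a-3p (785.5 ± 619 against 419 ± 416) and miR-140-5p (358 ± 113 against 222 ± 90.5) had log2 fold changes of 0.80 ± 0.37, 1.24 ± 0.67 and 0.75 ± 0.43 (SE). That of miR-140-5p was 0.486 without non-ulcerated sample 5 and 0.414 without 2 samples with low control or total signal. Of the values of miR-574-5p, 2 non-ulcerated ones lay under the floor, and raised to it they gave a difference of 0.520. With each sample left out in turn, the log2 fold change of miR-574-5p ran from 0.636 to 0.943. Its highest value over the alternatives, 2.79, came with the floor subtracted and rests on the values under the floor.

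**Figure D2:**
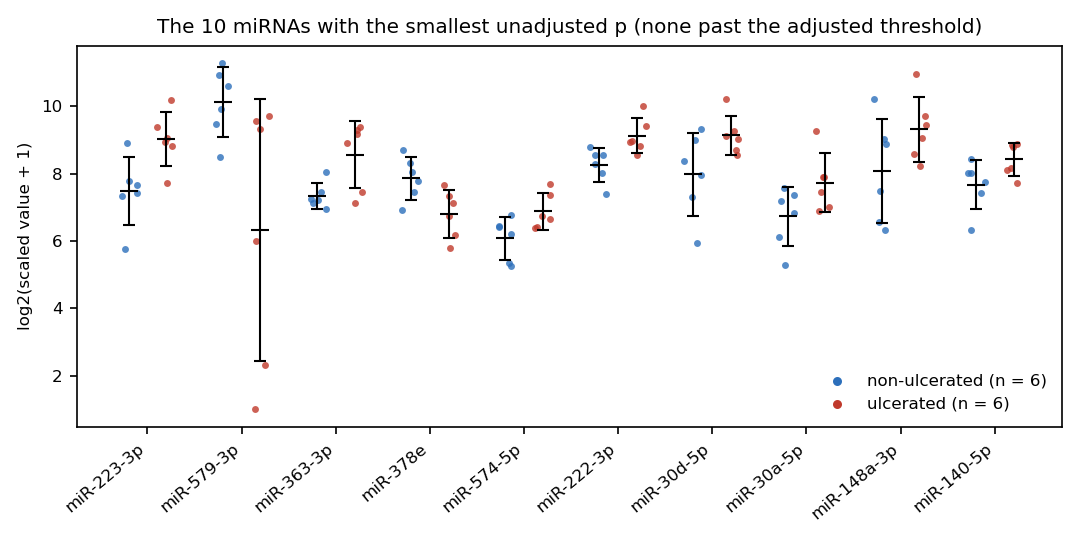
The 10 miRNAs with the smallest unadjusted p in non-ulcerated (blue, n = 6) and ulcerated (red, n = 6) tumours. Each point is 1 sample, on a vertical axis of log2(scaled value + 1), with the mean as the long bar and whiskers of ± 1 SD; miR-579-3p, whose probe carries a subtracted correction, has the widest spread, and none of the 10 passed the adjusted threshold.

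No leukocyte miRNA other than miR-223-3p had an unadjusted p under 0.05. miR-142-3p, expressed across blood cell lineages, averaged 499 ± 316 (SD, n = 6) in ulcerated and 495 ± 447 (SD, n = 6) in non-ulcerated tumours, a log2 fold change of 0.23 ± 0.65 (SE). It turned to -0.044 with quantile normalisation and ran from -0.18 to 0.62 with 1 sample left out. The lymphocyte miRNA miR-150-5p had a log2 fold change of -0.07 ± 0.69 (SE). It turned to 0.18 after rescaling to the messenger RNA probes or the ligation controls and ran from -0.50 to 0.29 with 1 sample left out. miR-155-5p, induced on activation of lymphocytes and macrophages, had one of 0.28 ± 0.58. It turned to -0.073 without non-ulcerated sample 1 and to -0.024 without 2 samples with low control or total signal. miR-146a-5p, a feedback regulator of inflammatory signalling, averaged 3115 ± 2171 against 1943 ± 1165, with a log2 fold change of 0.68 ± 0.59. It was 0.338 without non-ulcerated sample 5 and turned to -0.15 with array weights. Among lymphocyte miRNAs, miR-181a-5p had the highest, 0.76 ± 0.44 (SE), and the probe for miR-181b-5p and miR-181d-5p had 0.58 ± 0.39. The erythrocyte miRNA miR-451a averaged 1599 ± 2128 in ulcerated and 581 ± 361 in non-ulcerated tumours, a log2 fold change of 0.66 ± 0.82 that was 0.072 without ulcerated sample 1. Of the 2 tested members of the myeloid list, miR-223-3p alone passed when adjusted over the list alone (limma adjusted p = 0.0199), and 0 passed over all 115 miRNAs.

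Epidermal and stromal miRNAs did not separate the groups either. miR-203a-3p, which promotes keratinocyte differentiation, averaged 756 ± 463 (SD, n = 6) in ulcerated and 936 ± 898 (SD, n = 6) in non-ulcerated tumours. miR-205-5p, a miRNA of basal epithelium, averaged 1932 ± 1620 against 1838 ± 2322. The log2 fold changes of miR-203a-3p, miR-205-5p and miR-200c-3p were -0.11 ± 0.66, 0.31 ± 0.65 and -0.14 ± 0.54 (SE), and those of miR-203a-3p and miR-200c-3p turned positive after rescaling to the messenger RNA probes (0.14 and 0.12) or to the ligation controls (0.14 and 0.11). Both rescalings rest in part on ulcerated sample 6, which read lowest on both sets of probes. With 1 sample left out, each of the 3 miRNAs changed sign: they ran from -0.37 to 0.31, from -0.040 to 0.80 and from -0.40 to 0.28. The smooth muscle miRNA miR-145-5p had 0.14 ± 0.78, which turned to -0.39 without ulcerated sample 4 and changed sign in 6 of 31 alternatives. The endothelial miRNA miR-126-3p had 0.39 ± 0.58 (SE), or 0.056 without ulcerated sample 4 and -0.041 with array weights. miR-21-5p, raised in many solid tumours and in healing skin, averaged 3972 ± 1270 against 2888 ± 1673, a log2 fold change of 0.74 ± 0.54 that was 0.27 without non-ulcerated sample 5 and 0.112 with array weights. miR-221-3p, which shares its seed sequence with miR-222-3p, had 0.43 ± 0.58, or 0.092 without non-ulcerated sample 3. Of the 20 miRNAs named before the data were examined, 14 were tested; 0 passed over all tested miRNAs and 0 when adjusted over the list alone, where the smallest limma adjusted p was 0.139.

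The remaining 6 of those 20 miRNAs exceeded the floor in too few samples for the main test. miR-204-5p, a melanocyte miRNA, averaged 97.3 ± 53.7 (SD, n = 6) in ulcerated and 28.2 ± 27.6 (SD, n = 6) in non-ulcerated tumours, and differed before adjustment only (exact permutation test, p = 0.0303, adjusted p = 0.104 over 6 miRNAs). All 6 non-ulcerated values lay under the floor, so the size holds only against it. With values under the floor raised to it, the mean log2 difference was 0.57 (exact permutation test, p = 0.0606). It exceeded the floor in 4 ulcerated and 0 non-ulcerated tumours (Fisher's exact test, p = 0.0606, adjusted p = 1 over 64 probes). The adjusted value decides nothing, because these probes exceeded the floor in only 1 to 5 samples and none could pass alone. Its relative miR-211-5p, transcribed from within the melanocyte gene TRPM1, averaged 16.8 ± 7.31 against 27.7 ± 7.0 and never exceeded the floor (exact permutation test, p = 0.0346, adjusted p = 0.104). The hypoxia miRNA miR-210-3p, the wound-edge miRNA miR-31-5p and the muscle miRNA miR-1-3p never exceeded the floor in any sample. miR-143-3p, a smooth muscle miRNA read by a corrected probe, exceeded it in 2 samples of each group and averaged 248 ± 506 against 166 ± 256 (SD, n = 6; exact permutation test, p = 0.697).

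Among the 21 lists of miRNAs by cell type, family or genomic cluster, 10 had at least 3 tested members, and 2 of them passed the competitive test camera with its preset correlation. The list of miRNAs described as oncogenic in melanoma shifted upward: 7 of its 7 tested members had positive log2 fold changes, ulcerated over non-ulcerated (6 of 7 with quantile normalisation), 0 of them past the threshold alone, with a mean log2 fold change 0.55 above the other miRNAs (camera adjusted p = 0.0447). It did not pass with an estimated correlation (adjusted p = 0.767). Its members with the smallest p were miR-222-3p, miR-30d-5p and miR-21-5p. The list of the cluster from miR-506 to miR-514 on the X chromosome, abundant in melanocytic tumours, shifted downward by a mean of -0.51 against the other miRNAs (camera adjusted p = 0.0447), and did not pass with an estimated correlation (adjusted p = 0.767). All 8 of its tested members had negative log2 fold changes, with 3 of the 8 turning positive after rescaling to the messenger RNA probes or to the ligation controls, and 0 passed alone. Among them miR-509-3-5p averaged 60.5 ± 54.7 (SD, n = 6) against 96.7 ± 54.7 (SD, n = 6), a log2 fold change of -0.89 ± 0.67 (SE), and miR-506-3p and miR-508-3p had -0.47 ± 0.60 and -0.41 ± 0.67. With 1 sample left out they ran from -1.36 to -0.448, from -0.921 to -0.240 and from -0.969 to -0.167. Of the values of miR-509-3-5p, 4 ulcerated and 2 non-ulcerated ones lay under the floor, and raised to it they gave a difference of -0.32. The same step moved the other way for miR-506-3p (-0.58) and miR-508-3p (-0.62).

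Neither list passed in limma's rotation test fry, which asks whether the members of a list move one way on balance (adjusted p = 0.849 for the oncogenic list and 0.905 for the miR-506 to miR-514 list). The ligation controls, with a mean log2 difference of -0.25 in ulcerated tumours, moved in the same direction as the latter list. That list still passed camera after rescaling to them, which does not test ligation as a cause. Rescaling a sample by a single factor moves all its miRNAs nearly alike, while camera sets a list against the other miRNAs. With the preset correlation, both lists passed under each of the 4 other scalings run with camera, which for the same reason is little test of scaling. Adjusted p was 0.0151 to 0.0393 for the miR-506 to miR-514 list and 0.0102 to 0.0415 for the oncogenic list. With each sample left out in turn, the miR-506 to miR-514 call was lost in 7 of 12 fits (adjusted p of 0.0551 to 0.159 in limma's camera) and the oncogenic call in 5 of 12 (0.0553 to 0.120), and neither held without ulcerated sample 1, ulcerated sample 2 or non-ulcerated sample 3. The mean shift of the former list ran from -0.81 without non-ulcerated sample 5 to -0.31 without non-ulcerated sample 3, and with no filter it was -0.17 and did not pass (camera adjusted p = 0.538).

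The miR-17-92 cluster and its paralogs had positive log2 fold changes for 8 of 8 tested members, among them miR-363-3p and miR-25-3p (679 ± 431 against 366 ± 140, SD, n = 6). The list did not pass (camera adjusted p = 0.0582, and 0.767 with an estimated correlation), but passed under each of the 4 other scalings run with camera (quantile, 100 most abundant, total and ligation controls, with adjusted p of 0.0291 to 0.0394). Its mean shift against the other miRNAs stayed nearly the same, at 0.415 as deposited and 0.397, 0.415, 0.414 and 0.415 under these scalings. miR-19b-3p, with the smallest difference of the 8, turned negative under 4 of 6 other scalings. The miR-29 and miR-30 families likewise had 8 of 8 positive members (7 of 8 under median-of-ratios rescaling). They did not pass as deposited (camera adjusted p = 0.0913, and 0.767 with an estimated correlation) but did under 3 of these 4 scalings (0.0291 to 0.142 over the 4). The counts of positive members stand beside 75 positive of the 115 tested miRNAs as deposited, a share that itself moved with the scaling. Lymphocyte miRNAs had 5 positive and 1 negative member, from 4 and 2 to 6 and 0 under other scalings (adjusted p = 0.287, and 0.00367 with no filter). Skin wound repair miRNAs had 12 and 2, from 9 and 5 to 14 and 0 under other scalings (adjusted p = 0.484, and 0.00367 with no filter), hypoxia miRNAs 1 and 2, or 0 and 3 with quantile normalisation (0.438), and keratinocyte and epithelial miRNAs 1 and 3 (0.538), the last becoming 4 and 0 after rescaling to the messenger RNA probes or the ligation controls. The let-7 family had 5 positive and 4 negative members (4 and 5 with median of ratios). Its median was 0.13, while its mean against the other miRNAs was -0.03, the downward direction of camera (adjusted p = 0.868). Fibroblast and smooth muscle miRNAs had 7 positive and 1 negative member, a mean 0.02 above the other miRNAs against a downward direction in camera (adjusted p = 0.960, and 0.0184 with no filter at a mean 0.31 above), 4 and 4 after rescaling to the total and 3 and 5 with quantile normalisation.

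**Figure D3:**
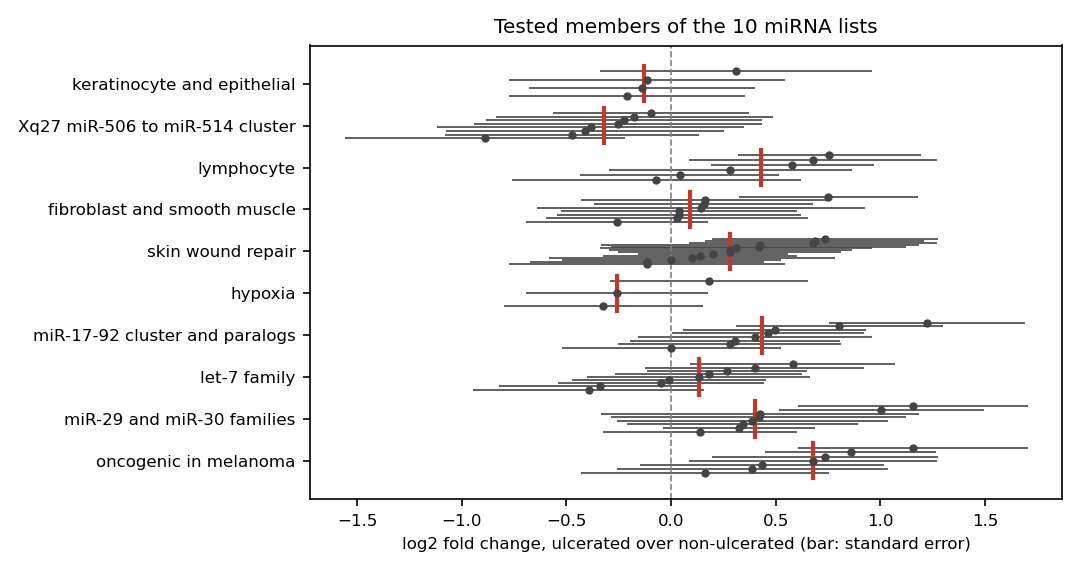
Log2 fold changes, ulcerated over non-ulcerated, of the tested members of the 10 miRNA lists. Each point is 1 miRNA with its standard error as a horizontal bar, the red mark is the median of the list and the dashed line is 0; the oncogenic list has 7 of 7 members to the right of 0 (6 of 7 with quantile normalisation) and the miR-506 to miR-514 cluster 8 of 8 to the left (5 of 8 after rescaling to the messenger RNA probes or ligation controls).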

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

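The tests on miR-223-3p, on the corrected probes and on the probes below the floor were chosen after these results were seen; the splits of the samples were also set against counts already known.

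In 3 of the 78 groups of 6 values examined, 1 sample lay far from the other 5, and chance alone marks about 1 group in 20. miR-145-5p read 2600 in 1 ulcerated tumour against 209 to 465 in the others, a gap of 0.683 of the whole range on the log2 scale. miR-221-3p read 65 in 1 non-ulcerated tumour against 223 to 323, a gap of 0.768 on the same scale. The number of miRNAs above the floor was 77 in 1 non-ulcerated tumour against 117 to 140, a gap of 0.635. Outside the tested set, miR-143-3p reached 1275 in 1 tumour with 599 as the next value, and miR-494-3p reached 976 with 274 as the next, although neither exceeded the floor in 6 samples. Both are read by corrected probes, whose lowest value was the bound of 1 in each group.

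miR-223-3p had the smallest p, with a log2 fold change of 1.54 ± 0.53 (SE), and did not pass adjustment over all 115 miRNAs. Scaling as the whole cause is argued against, since the lowest value over 6 other scalings was 1.41. More leukocytes of every kind as the whole cause stays undecided, because miR-223-3p was chosen as the smallest p in these same samples. miR-223-3p was set over the mean of the 7 other tested members of the myeloid and lymphocyte lists, miR-181a-5p and the miR-181b-5p and miR-181d-5p probe included. This ratio was 1.19 ± 0.47 (SE) higher on the log2 scale in ulcerated tumours, in 6 of 6 above the non-ulcerated median. Its p takes no account of that choice (exact permutation test, p = 0.0152). Over the 5 others without the miR-181 probes, the difference was 1.31 ± 0.53. Blood in the tissue stays open, since with the erythrocyte miRNA miR-451a as a covariate the log2 fold change was 1.46 with a standard error of 0.56, too wide to exclude a fall to 0.77, which is 50% of the effect. As a hypothesis, neutrophils at the ulcerated surface may account for the difference, which these data neither test directly nor separate from chance.

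miR-579-3p and miR-378e were lower in 6 of 6 ulcerated tumours than the non-ulcerated median, and both probes carry a subtracted correction. Whether the subtraction set the size of either difference cannot be told apart from a difference of the miRNA itself: adding back a nearly constant amount shrinks any log2 fold change, so the added-back values of -0.49 ± 0.20 and -0.37 ± 0.16 (SE), against -3.80 and -1.06 as deposited, do not decide it. After scaling to the positive controls, POS_A differed by 1.03-fold at most, while the added-back values spanned 2.36-fold and 1.99-fold. A leftover in proportion to POS_A would thus be nearly constant and could not alone give these spans. The scaling largely set this outcome in advance, so it is no separate test. The added-back values of the 2 probes followed each other over the 12 samples (Pearson r = 0.976, permutation p = 1e-05, the smallest the resamples can give; Spearman rho = 0.951, p = 2e-05; adjusted over 3 relations 3e-05 and 6e-05; r = 0.947 without the 2 samples farthest from the median, and 0.890 and 0.991 within the groups), so they may share a signal that is not specific to either miRNA.

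The 619 probes that never passed the floor read lower in ulcerated tumours by a mean log2 of -0.21 (exact permutation test, p = 0.0887, adjusted p = 0.312 over 8 measures). Scaling or optical background of the lanes and a biological difference cannot be told apart for these probes: over the negative controls the difference of the 605 uncorrected ones was -0.13 (SD 0.13 and 0.17, exact permutation test, p = 0.152). Lower ligation efficiency also stays open, since over the ligation controls the difference was 0.043, with SDs of 0.30 and 0.15 that are too wide to decide (exact permutation test, p = 0.747). Over the 12 samples, ligation controls and these probes gave r = 0.599 (permutation p = 0.0367, adjusted p = 0.055) and rho = 0.378 (p = 0.226, adjusted p = 0.32), but r was -0.02 without the 2 samples farthest from the median, so the relation rests on those samples. miR-211-5p had the lowest difference of the 605 uncorrected probes, but values this close to background give no size, and it did not pass adjustment (exact permutation test, adjusted p = 0.104).

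Other splits of the 12 samples into 6 and 6 were drawn, 100 of 462 with the real one included. At an unadjusted p under 0.05, 35 splits gave at least the 5 miRNAs of the real one, and the highest other gave 42, so chance could not be excluded for this count. For lists passing camera, 33 splits gave at least the 2 of the real one, and the highest other gave 5, so chance could not be excluded here either. For miRNAs past the adjusted threshold the comparison is empty, because the real split called 0 and any split, 100 of 100, must call at least as many. Of the 99 other splits 10 called any miRNA, 3 called more than 1 and the highest called 13, which may reflect a structure among the samples or chance among correlated miRNAs, and this was not tested.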

How the results depend on the processing

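Rescaling to the ligation controls, the changes to corrected probes, the removal of 2 samples together, the miR-451a covariate and the raising of values to the floor were chosen after seeing the data; the other alternatives were planned. The count of miRNAs past the threshold was 0 under 32 of 32 alternatives, with smallest adjusted p from 0.145 to 0.998. The count at an unadjusted p under 0.05 moved from 5 to 8 with median of ratios, 9 with quantile normalisation, 10 with the 100 most abundant miRNAs, 8 with the total, 14 with array weights (2 up and 12 down), 8 by exact permutation, 74 with no filter (7 up and 67 down of 798), 1 with the floor exceeded in all samples, 2 with a floor 5 times as high, 13 with the ligation controls (12 up and 1 down) and 8 with the correction added back. It was 8 without ulcerated sample 1 and 3 without ulcerated sample 3. Scaling shifted the median log2 fold change from 0.16 (65.2% positive) to 0.02 (51.3%) with median of ratios, 0.03 (51.3%) with quantile, 0.07 (56.5%) with the 100 most abundant, 0.04 (54.8%) with the total, 0.41 (80.0%) with the messenger RNA probes and 0.40 (80.0%) with the ligation controls. Array weights gave -0.18 (28.7%) and no filter -0.16 (28.4%). It also turned negative without ulcerated sample 3 (-0.019, 45.2%), ulcerated sample 4 (-0.031, 46.1%) or non-ulcerated sample 5 (-0.098, 40%). The cause was not tested. Background limits this, as 619 of 798 probes never passed the floor.

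The count of lists past the threshold moved from 2 to 0 with an estimated correlation, 0 with fry, 4 each with quantile normalisation, the 100 most abundant and the total, 7 of 21 with no filter, 0 with the floor exceeded in all samples, 0 with the correction added back, and 1 without the 2 samples with low control or total signal. Leaving out each sample gave 0 to 3 lists: 0 without ulcerated sample 2 or non-ulcerated sample 3, and 1 without ulcerated sample 1 (the miR-17-92 list) or non-ulcerated sample 1, 5 or 6. The lists gained with quantile normalisation, the 100 most abundant and the total were the miR-17-92 and the miR-29 and miR-30 lists, the former also with the ligation controls and in 4 of 12 fits without a sample, the latter in 2 of 12. With no filter more lists were testable. The lymphocyte (adjusted p = 0.00367), skin wound repair (0.00367) and fibroblast (0.0184) lists then passed too, while the miR-506 to miR-514 list did not (-0.17, 0.538). They were set against probes at background. The difference in total signal turned to -0.17 for the median over probes, and that in detected miRNAs to 2.33 and 3 with a floor 2 and 5 times as high. miR-211-5p, never above the floor, passed over its 6 miRNAs with median of ratios (adjusted p = 0.0130) and the total (0.039). This is rescaled background, not a call. Its other settings reached 0.721. miR-204-5p did not pass (0.0779 to 0.333). The cause of the other shifts was not tested.

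Of the 25 named and tested miRNAs, 0 passed under any alternative and 9 changed sign under at least 1. Messenger RNA rescaling turned miR-203a-3p to 0.14, miR-200c-3p to 0.12 and miR-150-5p to 0.18. Ligation control rescaling turned the same 3 to 0.14, 0.11 and 0.18. Array weights turned miR-142-3p to -0.26, miR-146a-5p to -0.15, miR-145-5p to -0.21 and miR-126-3p to -0.041. Quantile normalisation turned miR-142-3p to -0.044. Without the 2 samples, miR-155-5p was -0.024, miR-145-5p -0.071 and the let-7 family mean 0.053. The covariate turned miR-150-5p to 0.018 and miR-145-5p to -0.14. Leaving out each sample gave -0.37 to 0.31 for miR-203a-3p, -0.040 to 0.80 for miR-205-5p, -0.40 to 0.28 for miR-200c-3p, -0.073 to 0.59 for miR-155-5p, -0.50 to 0.29 for miR-150-5p, -0.18 to 0.62 for miR-142-3p and -0.39 to 0.60 for miR-145-5p. For list means against the other miRNAs it gave -0.39 to 0.26 for keratinocyte, -0.14 to 0.19 for fibroblast and -0.11 to 0.052 for let-7 miRNAs. The fibroblast mean turned to -0.031 with quantile normalisation, -0.10 with the floor exceeded in all samples, -0.00593 with the correction added back and -0.033 without the corrected probes. The let-7 mean turned to 0.23 with no filter. The cause was not tested. Models for raw counts and a fit without rescaling were not run as alternatives, because the values are not raw counts and the main fit already does not rescale. No paired analysis was possible, as the labels give no pairs.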

Other observations

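Large parts of the panel stayed below the background floor in these tumours. Of the imprinted miRNA cluster on chromosome band 14q32, 56 of 62 probes never exceeded the floor, and of the placental cluster C19MC 36 of 36 never did. Liver miRNAs (3 of 3), skeletal muscle miRNAs (6 of 7), neural miRNAs (5 of 6) and the miR-34 family (5 of 7) were also mostly or wholly below it. So were 3 of 4 melanocyte lineage probes, with miR-204-5p as the exception, and 3 of 4 of the miR-183 cluster. Of the miR-506 to miR-514 cluster, 10 of 19 probes never exceeded it and 8 were tested. The 2 tested members of 14q32 had a median log2 fold change of 0.05, the 2 endothelial ones 0.27, the 2 myeloid ones 0.89, and the single tested members of the erythrocyte, miR-34 and neural lists 0.66, -0.11 and 0.85.

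The same ulcerated tumour held the highest value of 2 erythrocyte miRNAs. It read 5721 for miR-451a, with 1740 as the next value, and 190 for miR-144-3p, with 55 as the next. Over the 12 samples miR-451a and miR-223-3p did not pass a test of their relation (r = 0.311, permutation p = 0.326; rho = 0.315, p = 0.32; both unchanged after adjustment over 3 relations; r = 0.206 without the 2 samples farthest from the median, 0.497 within ulcerated and -0.10 within non-ulcerated tumours).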
